A study of Mus musculus with 12 samples.

How the data were processed

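Bulk hippocampus of 12 male mice was profiled by RNA sequencing of polyA RNA, with 6 wild-type (WT) animals and 6 animals with a conditional knockout (cKO) of the microRNA cluster that runs from Mir379 to Mir410. Per the labels' protocols, RNA was extracted with Trizol and chloroform and libraries were made with a NEB Next Ultra RNA kit. The authors deposited estimated read counts per gene symbol, 1 column per animal, not scaled between libraries. Per the submitters' processing notes, Salmon 1.3.0 and the genome build GRCm38 were used. The transcript annotation, the strand setting and the way transcripts were summed to genes are not given in the sources used here. Between 24.8% and 25.9% of a library's values differed from a whole number, so the deposited expected counts were rounded to whole numbers before any count model. All 12 columns were used. Some single genes are not reported here.

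The table held 33250 gene symbols, of which 32940 were found in the GENCODE annotation of GRCm38 given for this work. That annotation supplied coordinates, gene types and 3′ UTR sequences. Without a stated strand setting, reads of overlapping genes on opposite strands cannot be separated, and reads shared by near-identical genes may have been split by the quantification.

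Genotypes were compared with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with TMM scaling and the default filterByExpr filter by genotype (a count minimum of 10 and a total of 15). The model held genotype alone, and p-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. Levels are given as TMM-scaled CPM, the count of a gene scaled to a common library total. The 38 gene lists were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, adjusted over the lists with at least 5 tested members. The fry test and a count of members adjusted over the list alone stand beside it. Library composition was compared by exact permutation tests, two-sided, on 5 measures adjusted together. The share of counts in transcript models annotated as yet to be experimentally tested was added after the data were seen, as a single unadjusted test.

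For the seed-site test, the longest annotated 3′ UTR of at least 50 bases was taken for each gene. Matches to positions 2 to 8 of 26 miRNAs of the cluster were counted, with sequences recalled from miRBase and not checked against a miRNA reference here. The slope of log2 fold change on log2(1 + sites) was fitted with UTR length, UTR GC content and mean expression as covariates. It was set against 1000 sets of 26 control 7-mers matched on base composition, with a total number of sites within 20% of the real total. The result is the number of control sets that lay as far from their mean, on either side.

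The steps were tested on simulated data. For 6 cKO against 6 WT with 19106 genes, edgeR recovered 92% of genes changed by 1 on the log2 scale in either direction. It recovered 82% of those raised by 0.5 and 80% of those lowered by 0.5, with 15 false calls among 200. Simulated genes were drawn independently of each other, and the changed ones had at least 1 CPM. The simulation held none of the structure shared between real libraries, so these shares are not the power of this comparison. In the simulated seed-slope comparison over 15264 genes, a slope of 0.05 added to shuffled fold changes came back as 0.0507.

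Library totals ranged from 42360558 to 51095758 counts. The p-values measure the spread between animals, which the labels number within each genotype. No pair of libraries within a genotype agreed within counting noise, with a chi-square per degree of freedom of at least 7.93 in every pair.

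The genes, lists, tests and most alternatives were fixed before the data were examined. Published targets of the cluster were listed from memory of the literature. Lists of contractile smooth muscle genes, other smooth muscle genes, pericyte markers, arterial endothelial genes and pan-neuronal genes were written after the fixed lists had been tested, for the tests of explanations. Named genes were Mirg, Meg3, Rian, Rtl1, Dlk1, Dio3 and Emx1, whatever their values, and up to 12 genes in each direction with the smallest p among those past the threshold with a mean of at least 1 CPM. If none passed in a direction, the 5 with the smallest p were named and said not to have passed. Up to 4 members with the smallest p of each list that moved or is discussed were named, and the list of published targets. Predicted genes and genes with Rik names under the second part are listed and not described. Gm37899, Ttr and Gm45110, single genes in lists of 5 or fewer, and B830012L14Rik where it is described as a gene of the targeted region, were chosen after their values were seen.

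Alternatives were RLE and upper-quartile scaling, library totals alone, DESeq2 1.42.0, limma-voom, other low-count filters, each of the 12 animals left out, animal number as a block, 1 or 2 surrogate variables from sva 3.50.0, a threshold of 0.1, robust dispersion and groups of genes left out. For lists, an estimated correlation and fry were added. For seed sites, other definitions of a site were used. A run without the 3 libraries lowest in choroid plexus signal and a run without cKO 1 with 2 surrogate variables were chosen after seeing the data.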

Results

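The data were estimated read counts for 33250 gene symbols in the hippocampus of 6 WT and 6 cKO male mice. In cKO animals, Cre recombinase under the control of Emx1, a homeobox gene of excitatory neurons and glia of the dorsal forebrain, removes the microRNA cluster from Mir379 to Mir410 in the imprinted Dlk1-Dio3 region. The comparison asks whether loss of the cluster in these cells changes gene expression in the tissue. The WT libraries 1 to 6 held 48763988, 42360558, 46124162, 50804033, 48665524 and 49188492 counts. The libraries labelled cKO 1 to 6 held 46771217, 45013258, 50408357, 48169733, 44803740 and 51095758 counts.

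Mirg, an annotated long intergenic non-coding RNA of which 14032 of 19697 bases lie within the cluster, did not differ between genotypes beyond the spread of the animals. It was at 30.7 ± 2.39 CPM in WT and 34.1 ± 7.31 CPM in cKO (SD, n = 6 each), with a log2 fold change of 0.15 ± 0.12 (SE) and an edgeR adjusted p of 0.738. The WT libraries 1 to 6 read 32.5, 28.7, 31.6, 28.4, 28.7 and 34.1 CPM, and the libraries labelled cKO 1 to 6 read 23.6, 34.0, 32.9, 46.4, 34.9 and 32.6 CPM. Mirg lies on chromosome 12 from 109729764 to 109749460 (GRCm38, plus strand), and the annotated miRNA genes of the cluster run from 109709060 (Mir379) to 109743795 (Mir410). Which bases were deleted is not given in the sources used here and cells without Cre keep the locus, so Mirg does not check the genotype labels. Meg3 (log2 fold change -0.04 ± 0.11), Rian (0.02 ± 0.09), Dlk1 (0.59 ± 0.40) and Dio3 (0.44 ± 0.40), other transcripts of the region, did not pass the threshold. Rtl1 had 1 to 13 counts per library and was not tested. In the list of the targeted region 5 of 6 tested members were higher in cKO, and camera gave an adjusted p of 0.303. Among 38 flanking genes 28 were higher (camera adjusted p = 0.138), and Dync1h1, Mok, Wdr25 and the others did not pass.

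**Figure D1:**
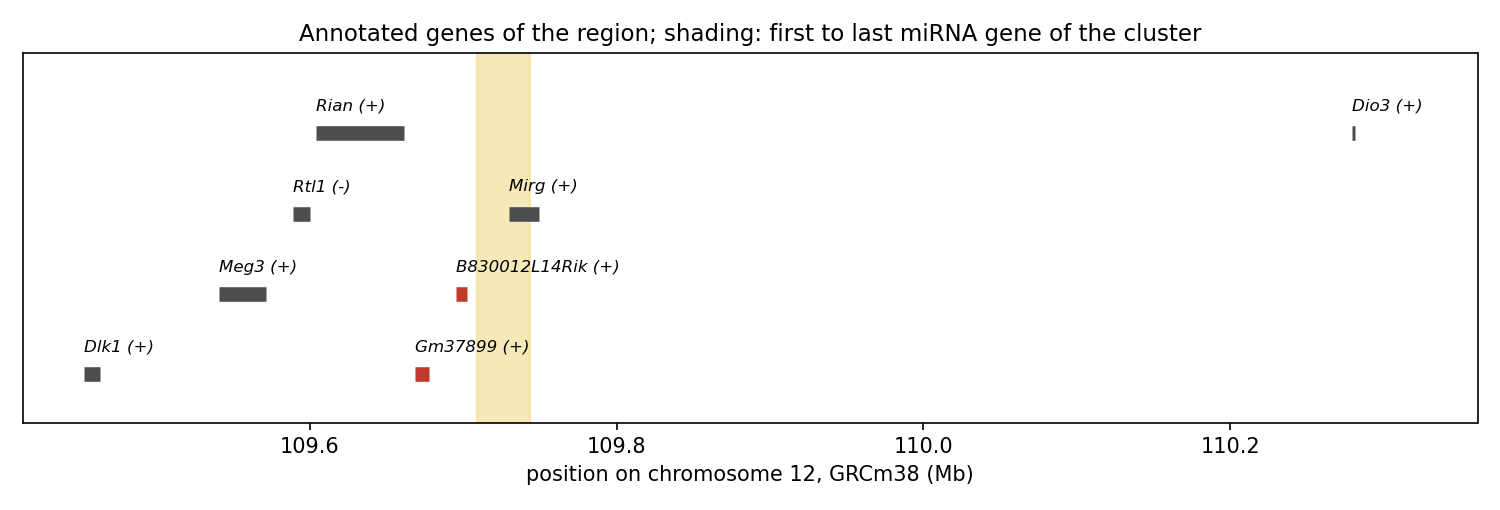
Annotated genes of the Dlk1-Dio3 region on chromosome 12 of GRCm38, with position in Mb on the x axis and strand in brackets; vertical placement only separates labels. The shading runs from Mir379 to Mir410, and the bars in red are Gm37899 and B830012L14Rik, which lie upstream of it.

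B830012L14Rik, an annotated long intergenic non-coding RNA, was higher in 5 of 6 libraries labelled cKO than in every WT library. It lies on chromosome 12 from 109695586 to 109702587 on the plus strand, and ends 6473 bases upstream of Mir379. Its level was 0.600 ± 0.186 CPM in WT and 16.7 ± 8.35 CPM in cKO (SD, n = 6 each), a log2 fold change of 4.78 ± 0.60 (SE) with an edgeR adjusted p of 0.0343. The library labelled cKO 1 had 0.788 CPM, within the WT range of 0.310 to 0.865 CPM, and the other 5 had 17.4 to 25.8 CPM. The same library stood with WT at Gm37899 and Emx1. For Gm37899, a transcript model yet to be tested, at 109668869 to 109677585 on chromosome 12, it had 1.96 CPM against 6.13 to 8.19 CPM in the other cKO libraries. For Emx1 it had 9.14 CPM against 5.91 to 6.84 CPM. No WT library reached the levels of cKO 2 to 6 at B830012L14Rik. Directions given for cKO therefore include 1 library that did not show these differences. With all 12 libraries Gm37899 and Emx1 did not pass in edgeR (adjusted p = 0.177 and 0.308). Without the library labelled cKO 1 the log2 fold changes were 5.03 for B830012L14Rik, 1.97 for Gm37899 and -0.53 for Emx1. That library stood out by its values at these same 3 genes, so the values without it describe the other 11 libraries and are no test of the genes.

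**Figure D2:**
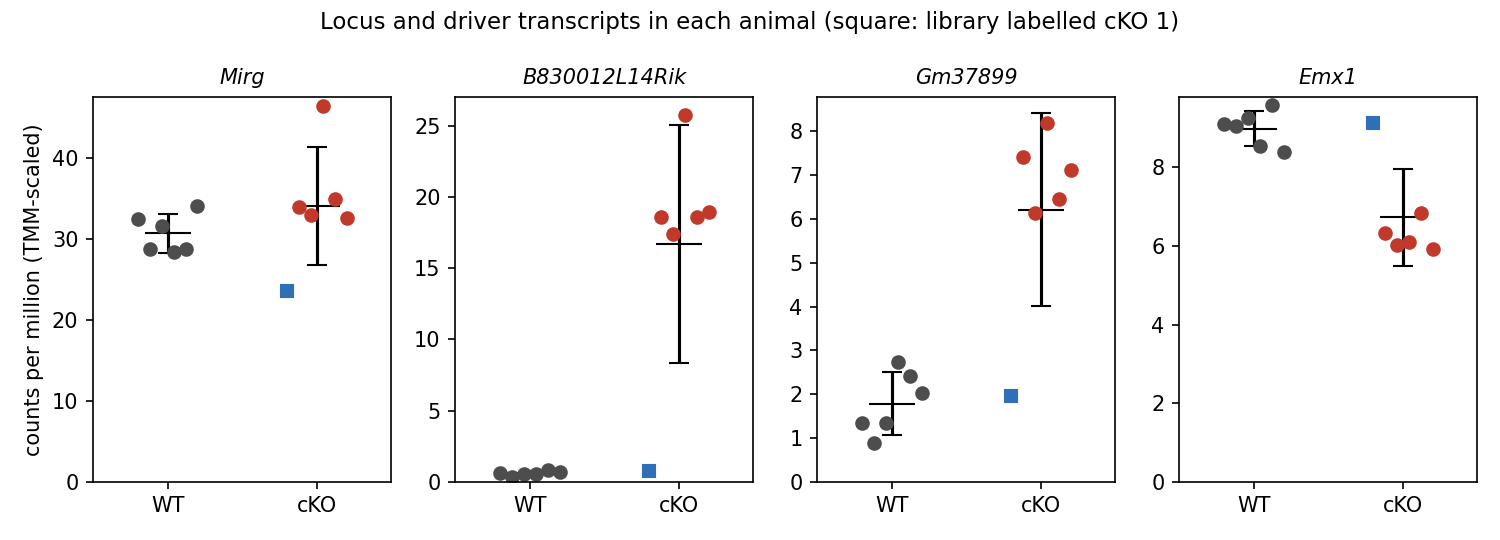
TMM-scaled CPM of Mirg, B830012L14Rik, Gm37899 and Emx1 in 6 WT and 6 cKO animals, 1 point per animal, with the group mean and SD as bars. The square is the library labelled cKO 1, which has 0.788 CPM of B830012L14Rik against 17.4 to 25.8 CPM in cKO 2 to 6.

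Across the transcriptome, 2 of 19325 genes tested passed an adjusted p of 0.05 in edgeR, both higher in cKO. The other gene was Il10ra, the ligand-binding chain of the interleukin-10 receptor (chromosome 9 from 45253837 to 45269149), at 3.57 ± 0.105 CPM in WT and 4.70 ± 0.064 CPM in cKO (SD, n = 6 each). It was 1.31-fold higher, with a log2 fold change of 0.39 ± 0.05 (SE) and an edgeR adjusted p of 0.0409, and all 6 cKO libraries lay above every WT library. Its counts were 146 to 183 per library in WT and 211 to 243 in cKO. At such counts, counting noise alone gives a larger SD than either group showed. The small p of Il10ra therefore rests in part on an unusually small spread. At an unadjusted p under 0.05 there were 1843 genes, 618 higher and 1225 lower, where 966 are expected by chance. No gene passed as lower. The 5 with the smallest p in that direction, none of which passed, were Srsf11 and Pnisr, which encode splicing-related proteins, Wdr31, Gm49125 and Gm48368. Srsf11 was at 159 ± 3.77 CPM in WT and 146 ± 2.67 CPM in cKO (SD, n = 6 each), with an edgeR adjusted p of 0.206. DESeq2 called 87 genes, 24 higher and 63 lower, and both edgeR genes were among them, while limma-voom called 0 with 1847 genes at an unadjusted p under 0.05. Without the library labelled cKO 1 edgeR called 6 genes, among them the 3 at which that library stood apart, and without any other single library it called 0, with a smallest adjusted p between 0.0541 (without WT 1) and 0.207 (without WT 4) and 1257 to 2799 genes at an unadjusted p under 0.05.

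The largest coordinated difference was in the list of smooth muscle and pericyte genes, of which 16 of 17 tested members were higher in cKO. Acta2, smooth muscle alpha-actin, was at 17.9 ± 4.66 CPM in WT and 35.0 ± 6.44 CPM in cKO (SD, n = 6 each), a log2 fold change of 0.97 ± 0.16 (SE). Myl9, the myosin regulatory light chain, read 14.3 ± 2.10 and 21.5 ± 2.44 CPM. Lmod1, an actin nucleator of smooth muscle, had a log2 fold change of 0.87 ± 0.14, and Cnn1, calponin, of 1.17 ± 0.21. In each of these 4 genes all 6 cKO libraries lay above every WT library. Over all genes tested none of the list passed in edgeR, with adjusted p of 0.115 for Lmod1 and Myl9, 0.126 for Acta2 and 0.180 for Cnn1. Adjusted over the list alone, 11 members passed. The median log2 fold change was 0.61, with a camera adjusted p of 1.38e-16, an adjusted p of 0.233 with an estimated correlation, and a fry adjusted p of 0.0199.

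**Figure D3:**
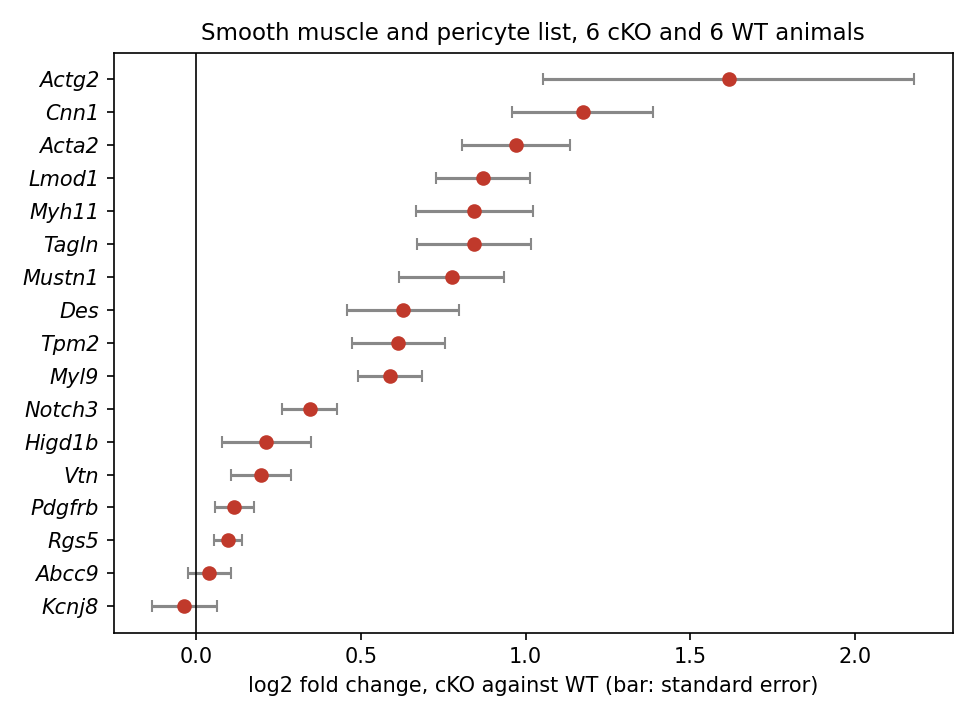
Log2 fold change of cKO against WT on the x axis for the 17 tested members of the smooth muscle and pericyte list, with 6 animals per genotype; points are edgeR estimates and bars are standard errors. Contractile genes such as Acta2 (0.97) and Cnn1 (1.17) lie above pericyte genes, which run from Kcnj8 (-0.04) to Notch3 (0.34).

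Non-muscle actomyosin genes, the list nearest to the study's title, did not move as a group. This list does not hold the smooth muscle genes Acta2, Myl9, Lmod1 and Cnn1, so its result does not cover them. Of 45 tested members 31 were higher and 14 lower, the median log2 fold change was 0.02, and the camera adjusted p was 0.378. The members went both ways, and adjusted over the list alone 1 higher and 1 lower member passed. Mylk, myosin light chain kinase, had a log2 fold change of 0.41 ± 0.07 (SE), Flna, an actin cross-linker, of 0.25 ± 0.07 and Rock2, a kinase that acts on myosin, of -0.14 ± 0.04. None of them passed over all genes tested, and adjusted over the list alone Mylk passed while Flna and Rock2 did not.

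Of the other lists, 5 passed camera as higher in cKO and none of these held with an estimated correlation. Meningeal fibroblast genes were higher in 13 of 13 members with a median of 0.36 (camera adjusted p = 0.000190), led by Col6a1 (0.57 ± 0.19), Fbln1, Fmod and Slc22a6, and the adjusted p was 0.740 with an estimated correlation. Endothelial genes were higher in 13 of 14 members with a median of 0.10 (camera adjusted p = 0.00157), among them Slc2a1, the glucose transporter of brain vessels (0.15 ± 0.05), Esam, Ly6a and Ly6c1, and the adjusted p was 0.700 with an estimated correlation. Glucocorticoid response genes were higher in 15 of 17 members with a median of 0.16 (camera adjusted p = 0.000131), with Plin4 at 0.55 ± 0.18 and Errfi1, Map3k6 and Sult1a1 next to it, and the adjusted p was 0.320 with an estimated correlation. Cholesterol synthesis genes (18 of 19 members higher, median 0.05, camera adjusted p = 0.0117), among them Dhcr7 and Sc5d, and cytosolic ribosomal protein genes (33 of 36, median 0.03, camera adjusted p = 0.0223), among them Rpl6, Rps27 and Rps18, had small differences. For both the adjusted p was 0.740 with an estimated correlation. Without WT 2, WT 3 and cKO 4, the libraries lowest in choroid plexus signal, the meningeal fibroblast and endothelial lists no longer passed camera (adjusted p = 0.150 and 0.399). The cholesterol list was lost without WT 1 (camera adjusted p = 0.0654), WT 2 (0.0673), WT 6 (0.0715), cKO 3 (0.0901) or cKO 5 (0.0654), and the ribosomal list without WT 3 (0.0867), WT 5 (0.476), WT 6 (0.165), cKO 1 (0.166) or cKO 6 (0.469). In these 5 lists no member passed on its own, over all genes or adjusted over the list alone.

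The ion channel, excitatory synapse, dentate granule neuron and oligodendrocyte lists passed camera as lower in cKO with the preset correlation. None of them held with an estimated correlation or with fry. Of 27 ion channel genes 21 were lower, with a median log2 fold change of -0.09 (camera adjusted p = 1.01e-05, adjusted p = 0.700 with an estimated correlation), and 7 passed adjusted over the list alone. Cacna1e, a voltage-gated calcium channel, was at 593 ± 50.5 CPM in WT and 497 ± 26.8 CPM in cKO (SD, n = 6 each). Kcnq3, Scn3a and Scn2a, potassium and sodium channels, had log2 fold changes of -0.26 ± 0.07, -0.22 ± 0.06 and -0.22 ± 0.07 (SE). Of 39 excitatory synapse genes 31 were lower, with a median of -0.05 (camera adjusted p = 0.000131, adjusted p = 0.740 with an estimated correlation). The glutamate receptor genes Gria2 (-0.19 ± 0.05), Grin2b (-0.24 ± 0.07) and Grm5 (-0.18 ± 0.06) and the adhesion gene Lrrtm2 led this list, and none passed adjusted over the list alone. All 13 dentate granule neuron genes were lower with a median of -0.16 (camera adjusted p = 0.00195, adjusted p = 0.740 with an estimated correlation), among them Prox1 (-0.20 ± 0.11), Dock10, Stxbp6 and Sema5a. All 16 oligodendrocyte genes were lower with a median of -0.10 (camera adjusted p = 0.0412, adjusted p = 0.740 with an estimated correlation), including Aspa, Opalin, Ugt8a and Gjc3. This list was lost without WT 1 (camera adjusted p = 0.202), WT 5 (0.368), cKO 4 (0.50) or cKO 5 (0.283), and its median was -0.15 without the library labelled cKO 1. Without WT 2, WT 3 and cKO 4, the libraries lowest in choroid plexus signal, the excitatory synapse and dentate granule lists no longer passed camera (adjusted p = 0.118 and 0.103), and the dentate list was also lost without cKO 4 alone (0.0891). Beside these lists, the share of counts in transcript models yet to be tested was 0.284 ± 0.0169% in WT and 0.264 ± 0.00788% in cKO (SD, n = 6 each), with an exact permutation p of 0.0281, two-sided and unadjusted.

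The 13 published targets of the cluster did not differ as a group, with 5 higher, 8 lower, a median log2 fold change of -0.02 and a camera adjusted p of 0.196. Dcx, a microtubule protein of young neurons, had -0.27 ± 0.11 (SE), Chrdl1 -0.17 ± 0.17, Cdh2 -0.08 ± 0.05, Creb1 -0.07 ± 0.04, Pum2 -0.07 ± 0.04, Dlgap3 -0.03 ± 0.04, Bdnf -0.02 ± 0.04 and Prr7 -0.01 ± 0.09. Foxp2 had 0.13 ± 0.23, Limk1 0.02 ± 0.08, Cnih2 0.02 ± 0.06, Src 0.01 ± 0.03 and Sv2a 0.00 ± 0.05. None passed over all genes or adjusted over the list alone.

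Lists of the other cell types and pathways did not pass camera. Inhibitory synapse and presynaptic vesicle genes both had a camera adjusted p of 0.0841, CA1 pyramidal genes (Neurod6, Man1a and Nov among them) had 0.176, and CA3 and CA2 pyramidal genes had 0.519. Microglia had 0.557, astrocytes 0.303, oligodendrocyte precursors 0.362, interneurons 0.844 and neurogenesis genes 0.519. Immediate early genes had 0.285, oxytocin, vasopressin and neuropeptide genes (Pnoc, Avpr1b, Trh and Tac1 among them) 0.122 (without the library labelled cKO 1 camera gave 0.00463, with 15 of 18 members higher and a median of 0.15, and 0.827 with an estimated correlation), extracellular matrix genes 0.591, circadian clock genes 0.335 and interferon response genes 0.225. Genes of the Emx1 locus had 0.140, oxidative phosphorylation 0.189, mitochondrially encoded genes 0.106 and heat shock genes 0.226. Dissection markers of thalamus, neocortex (Bcl11b among them) and striatum had 0.303, 0.177 and 0.357, blood had 0.189, and ependymal genes had 0.106. Choroid plexus genes (Aqp1, Cldn2, Calml4 and Otx2 among them) were higher in 15 of 15 members with a camera adjusted p of 0.235. Ttr, the main transcript of the choroid plexus, ranged from 49.8 to 7657 CPM within WT and from 28.3 to 5078 CPM within cKO. Without WT 2, WT 3 and cKO 4, the libraries lowest in this signal, edgeR called 0 genes with 1457 at an unadjusted p under 0.05, and 6 lists passed in place of 10, without the excitatory synapse, dentate granule, endothelial and meningeal fibroblast lists.

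Genes with seed sites of the cluster's miRNAs were compared with control sequences over 15264 genes with an annotated 3′ UTR, of which 11980 had at least 1 of 56263 sites. The slope of log2 fold change on log2(1 + sites) was -0.0015, and the control sets had a mean slope of -0.0050 with an SD of 0.0016. The slope lay 0.0034 above this mean, and 28 of 1000 control sets lay as far from it. With only sites followed by an A it was 4 of 200 control sets, and with any site against none 47 of 1000. With animal number as a block it was 16 of 1000, and with 1 surrogate variable 80 of 1000. With genes of at least 10 CPM it was 148 of 1000, and with sites counted per kilobase 494 of 1000. It was also over 50 of 1000 without WT 3 (93), WT 4 (117), WT 6 (59), cKO 3 (87) or cKO 6 (106). Genes are not independent replicates.

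Total count, genes with a count, the shares of the top 10 and top 100 genes and the mitochondrial share did not differ with genotype beyond the spread of the animals. Mitochondrially encoded genes took 7.44 ± 0.422% of counts in WT and 7.62 ± 0.276% in cKO, and the top 10 genes took 7.39 ± 0.358% and 7.66 ± 0.604% (SD, n = 6 each). The smallest adjusted p of these 5 measures was 0.736 by the exact permutation test, two-sided. The share in transcript models yet to be tested, given above, was not among the 5 and was lower in cKO at an unadjusted exact permutation p of 0.0281.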

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

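A library was set apart when its gap to the nearest other library of its genotype exceeded Dixon's 95% critical value for 6 samples, as a share of the group's range. This met 16 of 190 groups of 6 animals, where chance gives about 10, and 3 of the 16 were the library labelled cKO 1. The tests of a wrong label, of a swap and of the contractile genes in that library, the test on vessel tissue, and the check on smooth muscle genes under 5 CPM and on arterial endothelial genes were chosen only after the result was seen.

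The library labelled cKO 1 was set apart by B830012L14Rik at 0.788 CPM, Gm37899 at 1.96 CPM and Emx1 at 9.14 CPM. All 3 lay within the WT range. A swap with a WT library is argued against, since 0 WT libraries reached the lowest of cKO 2 to 6 at B830012L14Rik. On 100 genes chosen without this library and outside chromosomes 6 and 12, its position between the WT mean at 0 and the cKO mean at 1 was 0.227, within the WT positions of -0.065 to 0.586 and below those of cKO 2 to 6, 0.624 to 0.911. A wrong label or an animal without recombination is a candidate explanation. The library's mean level of contractile genes, 2.17 log2 CPM, lay narrowly above the highest WT library at 2.10 and below cKO 2 to 6, at 2.40 to 2.90. The WT libraries alone ran from 1.18 to 2.10, so this level cannot decide. Against a wrong label stands a single gene of unusually small spread, Il10ra, which also passed without this library (edgeR adjusted p = 0.0430). Il10ra read 4.58 CPM in the library labelled cKO 1. The highest WT library had 3.77 CPM and the lowest of cKO 2 to 6 had 4.68 CPM. These values keep the label open. Gm45110, on chromosome 7, passed in edgeR only without this library. Its level in this library is not given here, so it was not weighed.

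The 10 contractile smooth muscle genes had a median log2 fold change of 0.84 and the 7 pericyte markers of 0.12. Of these pericyte markers 6 were higher (fry adjusted p = 0.0409, camera adjusted p = 0.0955 with an estimated correlation). Smooth muscle genes outside the contractile apparatus had a median of 0.14 (95% bootstrap interval 0.03 to 0.27). They were themselves higher in cKO in 13 of 14 members. Camera gave an adjusted p of 0.00152, or 0.0184 with an estimated correlation, and fry 0.00386, adjusted over the lists written later. The 8 of them under 5 CPM in WT had 0.27 (0.18 to 0.32), and the 7 under 5 CPM over all 12 libraries had 0.27 (0.25 to 0.32). All lay below 0.42, the limit set from the contractile median. If these genes came from smooth muscle alone, this would argue against more smooth muscle cells as the whole cause. How much of their level comes from other cells of the tissue is not known here, and such a part would shrink their change. More smooth muscle cells therefore stay open. The bootstrap intervals resample the genes of a list, not the animals, so they hold no spread between animals. Endothelial markers had a median of 0.10 (0.04 to 0.15), which argues against more vessel tissue of every kind, but all 8 arterial endothelial genes were higher with a median of 0.33, so a larger share of arteries stays open. Of the 10 contractile genes 9 had a seed site, but their 14 sites lay at the 12.9th percentile of lists matched on 3′ UTR length, so direct release from the miRNAs may or may not contribute. A change in the contractile state of the cells and a difference in the arteries taken at dissection also stay open, untested.

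The lower excitatory synapse, ion channel and dentate granule lists all 3 still passed camera with the preset correlation after trends on gene length and GC content were removed. Their medians were -0.04, -0.06 and -0.15 against -0.05, -0.09 and -0.17 before, which argues against such a bias as the whole cause of these medians. Before that step none of the 3 passed camera with an estimated correlation (adjusted p = 0.740, 0.700 and 0.740). Whether these lists differ with genotype at all therefore stays open. Pan-neuronal genes had a median of -0.0047 (95% bootstrap interval over genes, not animals, -0.0390 to 0.0064). This neither reaches nor clearly excludes -0.0390, the value set for fewer neurons. With the share of transcript models yet to be tested as a covariate 2 of the 3 lists passed, and dentate granule genes had a camera adjusted p of 0.117 and a median of -0.09. Without WT 2, WT 3 and cKO 4, the libraries lowest in choroid plexus signal, the excitatory synapse and dentate granule lists no longer passed camera (adjusted p = 0.118 and 0.103), which was not weighed further. The share of transcript models yet to be tested was itself lower in cKO, and unspliced reads were not counted. A part for unspliced RNA therefore stays open, untested.

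Choroid plexus and composition values set cKO 4 apart, with Aqp1 at 1.03 CPM, Cldn2 at 0.802 CPM, 8.89% of counts in the top 10 genes and 21.6% in the top 100. Within WT, Cdh2 was low in WT 1 at 100.6 CPM, Prr7 was high in WT 2 at 21.0 CPM, and Esam at 13.7 CPM and Man1a at 56.9 CPM set WT 4 apart. Il10ra at 3.77 CPM, Opalin at 18.0 CPM and Ugt8a at 51.3 CPM were highest in WT 5, and Sult1a1 at 12.6 CPM in WT 6. Prr7 was low in cKO 5 at 13.7 CPM.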

How the results depend on the processing

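The runs without the 3 libraries lowest in choroid plexus signal (WT 2, WT 3 and cKO 4) and without cKO 1 with 2 surrogate variables were chosen after seeing the data. Both edgeR genes were kept under RLE, upper-quartile scaling, library totals, the strict filter and a threshold of 0.1. The count was 87 with DESeq2, 46 without cKO 1 with 2 surrogate variables, and 1 without a filter or with 2 surrogate variables. It was 0 with limma-voom, with robust dispersion, with mitochondrial, ribosomal, Gm and Rik genes left out, and without the 3 libraries, with 1847, 1811, 1454 and 1457 genes at an unadjusted p under 0.05. Leaving out single animals gave 0 to 6 genes, with 6 only without cKO 1. Equal animal numbers did not pair the libraries, since their correlations ran from -0.27 to 0.25 and 1 of 6 numbers matched best with its own. With the number as a replicate block edgeR called 0 genes with 1724 at an unadjusted p under 0.05, and 9 lists passed. The 10 lists became 0 with an estimated correlation, 1 with fry, 6 without the 3 libraries, and 8 to 17 with single animals left out (17 without WT 1). With the strict filter and with the replicate block the oligodendrocyte list had a camera adjusted p of 0.0598 and 0.0699, and with 1 or 2 surrogate variables the ribosomal list had 0.0776 and 0.0764. The smooth muscle list passed camera in each run with the preset correlation. The seed-site distance of 0.0034 lost its threshold with sites per kilobase (0.00051), at 10 CPM or more (0.0018), with 1 surrogate variable (0.0027) and without WT 3, WT 4, WT 6, cKO 3 or cKO 6, and ran from 0.0026 to 0.0046 with single animals left out. Mirg stayed above 0 and short of the threshold in all runs made, at 0.03 to 0.23. The cause of these changes was not tested. Counts near 0 limit Rtl1, which was not tested.

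Some genes that had not passed changed sign. Prr7 was 0.0014 with library totals, 0.014 with limma-voom, 0.0026 with the replicate block, 0.037 with 1 surrogate variable, 0.13 without the 3 libraries and 0.024 without cKO 1 with 2 surrogate variables. With 1 surrogate variable Ttr was -0.55, Otx2 -0.036 and Cldn2 -0.00099. Without the 3 libraries Dlgap3 was 0.022, Foxp2 -0.0045, Limk1 -0.016, Rian -0.048, Sv2a -0.019 and Ttr -0.032. Without cKO 1 with 2 surrogate variables Cnih2 was -0.0051, Foxp2 -0.041, Meg3 0.039 and Ttr -0.54. With single animals left out, Rian ran from -0.052 to 0.068, Src from -0.0092 to 0.014, Sv2a from -0.032 to 0.022, Limk1 from -0.032 to 0.056, Prr7 from -0.048 to 0.083, Ttr from -0.020 to 0.80, Cnih2 from -0.024 to 0.040, Meg3 from -0.12 to 0.028 and Foxp2 from -0.063 to 0.27. The difference in total count, cKO minus WT, was 59218, and was -32120 without mitochondrial genes and -998896 to 689799 with single animals left out. The difference in genes with a count ran from -172 to 0.6.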

Other observations

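The gene Gm45110 was chosen only after the result was seen, and the counts of splits were planned. Without the library labelled cKO 1, 6 genes passed in edgeR, 3 higher and 3 lower in cKO, but that library stood out by its values at 3 of them, which are not tested by leaving it out. Beside B830012L14Rik, Gm37899, Il10ra and Emx1 these included Gm45110, a transcript model yet to be tested on chromosome 7, at 2.16 ± 0.466 CPM in WT and 0.885 ± 0.103 CPM in cKO (SD, n = 6 and n = 5). With all 12 libraries only B830012L14Rik and Il10ra passed, so the others, Gm45110 included, passed only once that library was left out. The level of Gm45110 in the library labelled cKO 1 is not given here, so whether it stood with WT at this gene stays open. Emx1 lies on chromosome 6 from 85187438 to 85204462, and was 0.690 of its WT level without that library.

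Of 462 splits of the 12 libraries into 6 and 6, 100 were drawn, the real one included. The real 2 genes were matched by 4 of the 100 and the highest other split gave 1019, with WT 1 and WT 6 beside cKO 1, 2, 3 and 6, which points to a structure of the samples outside genotype. With only 100 of the 462 splits drawn and a mixed split at 1019 genes, this count does not exclude chance for the 2 genes. Of 100 splits of the 11 libraries without cKO 1, 3 gave at least 6 genes, and the highest other gave 89, which does not exclude chance, since the real 6 include the 3 genes by which cKO 1 stood out. The real 10 lists were reached or passed in 61 of 100 splits, with 22 in the highest, so the number of lists with the preset correlation is not beyond chance. The mean of the smooth muscle list, 0.58, was reached by 1 split, the real one, and the highest other was 0.45. This argues against chance for the list taken alone. Each split was scored on this list only, so the count takes no account of its choice as the largest of 38 lists. A seed-site slope as large in size came from 59 splits, the highest other being 0.0067, and a distance from the controls as large came from 5 splits, the highest other being 0.0051, so chance is not excluded for either.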
